A study of Mus musculus with 36 samples.

How the data were processed

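RNA from whole brain and from liver of male mice of 3 inbred strains was measured on Affymetrix expression arrays. The strains were C57BL/6J, AKR/J and DBA/2J. In each strain, mice kept awake for 6 h from light onset were set against controls left in their home cages, and both were killed 6 h after light onset, at Zeitgeber time (ZT) 6. Each array carried biotin-labelled cRNA from a pool of equal amounts of RNA of 3 mice, per the labels' protocols. The 12 groups (2 tissues, 3 strains and 2 conditions) held 3 pools each, and thus 9 mice each, which makes 108 mice if each tissue came from its own animals. Replicates were therefore separate pools, and their spread is that between pools of 3 mice and not between single mice. The labels of 4 AKR/J control arrays, numbers 2 and 3 in each tissue, conflict: the source name gives ZT 0, while the title and the study's design give ZT 6. These arrays were kept as ZT 6 controls and left out as an alternative.

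The values are log2 expression values made by the authors with RMA, per the submitters' processing notes; its version is not given in the sources used here. RMA is a method that subtracts background, gives the arrays processed together a common distribution and summarises the probes of each probe set on the log2 scale. It compresses the changes of dim probe sets and hides a change shared by most genes. Values lay between 2.12 and 14.91, with 0 missing. The median of all arrays was 4.78 in brain and 4.10 in liver, so the tissues appeared to have been normalised apart, and no expression level in brain was set against a level in liver. Only changes within a tissue were compared across tissues. No further normalisation was applied. Arrays carry no depth in the sense of sequencing, and the number of arrays limits the precision.

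Gene names came from the platform's annotation, updated by gene identifier through a reference table of the mouse assembly GRCm38.p6, of which names alone were used. Of 45101 probe sets, 64 control probe sets were left out of every test and 45037 were tested. Of these, 34945 had 1 gene symbol (34741 matched by gene identifier), 932 had several and 9160 had none. Genes were named from probe sets with 1 symbol, which covered 18193 genes, and 9010 genes had more than 1 such probe set. A gene was represented by its probe set with the highest mean over the 18 arrays of the tissue. Homer1 was reported for every probe set. Rbm3 was not analysed here.

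Each tissue was fitted apart with limma 3.58.1 in R 4.3.3, as 6 group means over 18 arrays with moderated variances. Limma's tests gave the effect of sleep deprivation averaged over strains, the effect in each strain, the strain by sleep deprivation interaction (an F test over the differences between strains) and the pairwise strain differences among controls. A fit over all 36 arrays and 12 groups tested whether the mean effect differed between liver and brain. P-values are two-sided and were adjusted over the 45037 probe sets by the Benjamini-Hochberg method, with an adjusted p under 0.05 as the threshold. Changes are log2 differences, sleep-deprived minus control unless stated, and values after ± are standard errors from limma with n = 3 arrays per group, except group means, which have SDs.

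Before the data were examined, 32 gene lists were fixed, of which 18 were pathway lists and 14 were cell type marker lists. In brain 24 lists were tested and in liver 23, each with at least 5 measured genes. Camera, a test in limma that compares the genes of a list with all other genes, was run on the mean effect with a preset correlation between genes of 0.01, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. The groups, comparisons, tests, alternative settings and rule for named genes were also fixed then. That rule took the 10 largest rises and 10 largest falls of the mean effect in each tissue with the same direction in all 3 strains. It took the 5 largest of each direction for each strain and each strain difference, the 10 smallest p of each interaction, up to 4 members of each list with the largest change, and a fixed set of genes. The fixed set was Homer1, Cirbp, Jph3, Ptgs2, Nptx2, Fos, Arc, Egr1, Bdnf, Per1, Per2, Dbp, Hspa5, Sgk1 and Fkbp5, besides Rbm3. Any further called member of a list that is named was chosen after its values were seen, as were the genes named under other observations. Probe sets without a gene name were counted and not named.

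The fits were tested on simulated data with the real spread and 200 changed probe sets. At a log2 change of 0.3 the mean effect was recovered for 46.3% of changed probe sets in brain and 50.7% in liver, and at 0.6 for 88.1% and 95.5%. Of the 164 and 175 probe sets called, 8 and 11 were false. In a strain alone, a change of 0.3 was recovered for 1.5% to 7.5%. An interaction of size 1 was recovered for 69.0% in brain and 81.5% in liver. The simulated noise was drawn independently for each probe set, so recovery on the real arrays may differ. For the effect in DBA/2J liver, 23 of 127 simulated calls were false.

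The alternative settings fixed in advance were a trended and robust variance prior, array quality weights, 1 probe set per gene, filters on dim probe sets, median centring, a repeated quantile normalisation, a fit on all 36 arrays, fits on the compared groups alone, an additive model of strain and condition, the replicate number as a block, strain differences averaged over both conditions, AKR/J left out, the AKR/J controls with a conflicting label left out, and each array left out in turn. For the lists they were also the estimated correlation, the rotation test fry and the mean of all probe sets of a gene. Alternatives without 3 brain arrays of narrow spread, without 2 brain arrays with raised 3' to 5' ratios, without all 5 of these and, for the liver lists and the tissue difference, without DBA/2J liver control 1 were added after the data were seen. Correlations used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.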

Results

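Gene expression was profiled in whole brain and in liver after 6 h without sleep in 3 inbred mouse strains, C57BL/6J, AKR/J and DBA/2J, with home-cage controls killed at the same time of day. The 36 arrays fell into 12 groups of 3, and each array held pooled RNA of 3 mice. Arrays of a tissue were closely alike, with correlations between arrays of 0.978 to 0.997 in brain and 0.980 to 0.996 in liver. Some arrays stood apart. In brain, 1 sleep-deprived array of each strain had a narrower spread of values (SD over probe sets of 1.91 in C57BL/6J array 1, 1.97 in AKR/J array 3 and 1.94 in DBA/2J array 2) than the other 15 arrays, at 1.98 to 2.06. Brain control array 2 of C57BL/6J and control array 3 of DBA/2J had larger differences between the 3' and 5' probe sets of beta-actin, a sign of RNA quality, at 1.13 and 0.98 on the log2 scale against 0.58 to 0.89 on the other 16. In liver this difference was 2.16 on DBA/2J control array 1 and 0.96 to 1.45 on the other 17. These 5 brain arrays and this liver array are called the doubted arrays, and results without them were added after the data were seen.

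**Figure D1:**
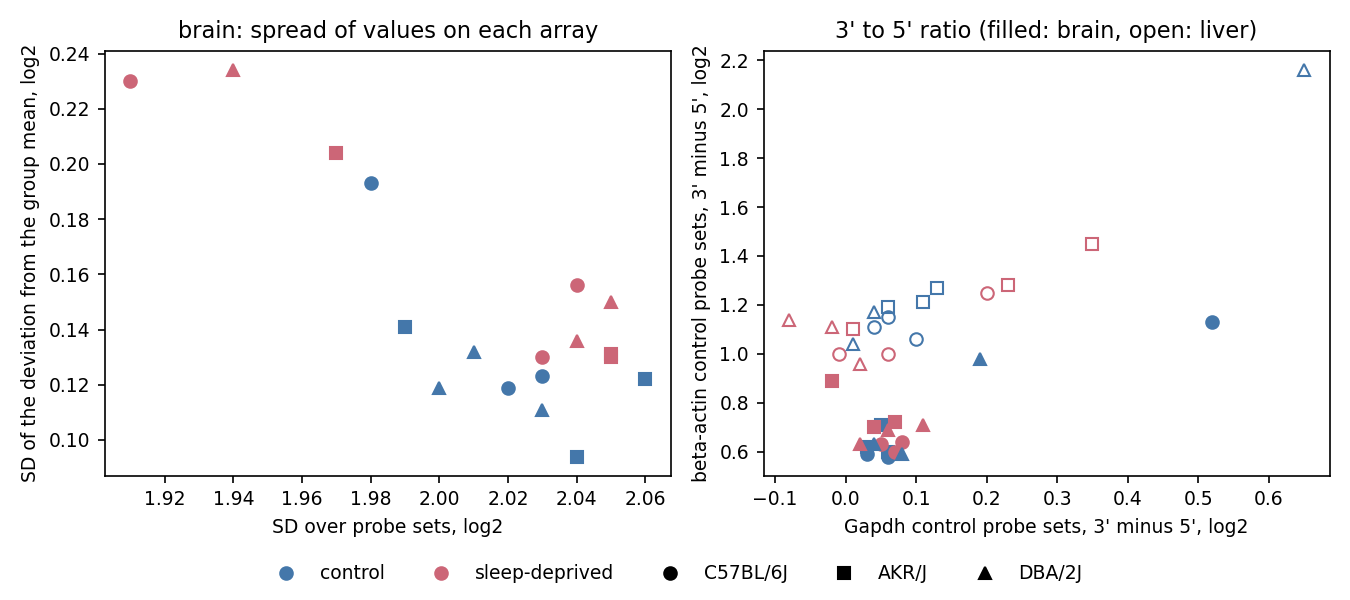
Left, for each brain array, the SD of its log2 values over all probe sets (horizontal) against the SD of its deviations from the group mean (vertical). Right, the 3' minus 5' difference of the Gapdh (horizontal) and beta-actin (vertical) control probe sets in log2 units for brain (filled) and liver (open), with colour giving condition and shape giving strain; the 3 narrow arrays reach the left panel's largest deviations, 0.204 to 0.234.

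The first comparison asked which transcripts respond to sleep loss in the brain across strains. The largest rise was that of Homer1, a synaptic scaffold gene that is induced by neuronal activity, on 1 of its probe sets, which rose by 2.44 ± 0.16 on the log2 scale, or 5.42-fold (adjusted p = 3.245e-07). Stress and chaperone genes followed. Hspa1b, an inducible heat shock protein, rose 2.69-fold (1.43 ± 0.15), Hspa5, the main chaperone of the endoplasmic reticulum (ER), rose 2.09-fold (1.07 ± 0.05), and Creld2, Hspb1, Sdf2l1 and Manf rose by 0.91 to 0.96. The activity-induced transcription factor Fosl2 rose by 0.95 ± 0.13, and Dio2, the enzyme that activates thyroid hormone in the brain, by 0.93 ± 0.08. Gm19439 (1.02 ± 0.10) and P4ha1 (0.91 ± 0.09), a collagen prolyl hydroxylase subunit, completed the 10 largest rises of genes ranked by their representative probe set, among which Homer1 is not counted. Among the falls, Cirbp, an RNA-binding protein induced by cold, was 2.46-fold lower (-1.30 ± 0.08, adjusted p = 1.588e-07). Opalin, a myelin protein of oligodendrocytes, fell by 0.95 ± 0.05, the clock output gene Dbp by 0.83 ± 0.07 and the transferrin receptor Tfrc by 0.67 ± 0.05. Parn, 2900055J20Rik, Zfp810, Zc3h6, Fbxl4 and Tipin fell by 0.60 to 0.73, Fbxl4 with an adjusted p of 0.0379. Each of these genes changed in the same direction in all 3 strains. Of the 20 genes so ranked, 11 had other probe sets, and for Hspa5, Fosl2, Dio2, Opalin, Tfrc and Zc3h6 some of these did not pass, while none passed in the other direction.

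In all, limma called 778 of 45037 probe sets, 310 higher and 468 lower, and by representative probe set 464 genes, 173 higher and 291 lower. Without the 3 arrays of narrow spread it called 1747, of which 1161 were higher, and 683 of the 778 were among them in the same direction; with AKR/J left out it called 85, without the 2 AKR/J controls of conflicting label 300, without AKR/J control array 1 479, and without the 2 arrays of raised 3' to 5' difference 439. Fbxl4 did not pass under 17 of 33 alternatives, and Fosl2, Tipin, 2900055J20Rik, Zc3h6 and Zfp810 did not pass with AKR/J left out (adjusted p = 0.1545, 0.1381, 0.1662, 0.1662 and 0.0982).

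Homer1 was represented by 6 probe sets, 5 of which rose in brain. The probe set with the largest change went from 5.67 ± 0.75 to 9.07 ± 0.24 in AKR/J, from 6.05 ± 0.37 to 8.67 ± 0.12 in DBA/2J and from 7.17 ± 0.14 to 8.46 ± 0.39 in C57BL/6J (log2, mean ± SD, n = 3). Its change within a strain passed in AKR/J (3.41, adjusted p = 2.150e-05) and DBA/2J (2.62, adjusted p = 4.516e-04) and not in C57BL/6J (1.29, adjusted p = 0.2632), while the interaction with strain had an adjusted p of 1.0000. Of the other probe sets, 4 rose by 1.03 ± 0.09, 0.58 ± 0.13, 0.37 ± 0.06 and, for the brightest, 0.34 ± 0.06, while the remaining probe set gave 0.37 ± 0.11 (adjusted p = 0.1120) and passed without the 5 doubted brain arrays (adjusted p = 0.0015). The probe set that rose by 1.03 read 2.84 to 3.37 on control arrays, near the lowest value of all, 2.12, so the size of its rise is uncertain. The probe set that rose by 0.58 did not pass under 15 of 32 alternatives, median centring and 12 single arrays left out among them. With AKR/J left out, it and those that rose by 0.37 and 0.34 did not pass (adjusted p = 0.3844, 0.1712 and 0.2247), while that with the largest change gave 1.95 (adjusted p = 1.279e-04). Which transcript each probe set detects was not analysed here. In liver none of the 6 passed, with changes of -0.09 to 0.15. There the probe set with the largest brain change had group means of 3.02 to 3.23, and that which rose by 1.03 had 2.84 to 3.06. Both lie near the lowest value of all, so low signal cannot be told apart from a lack of response. The brightest had liver group means of 6.21 to 6.65.

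**Figure D2:**
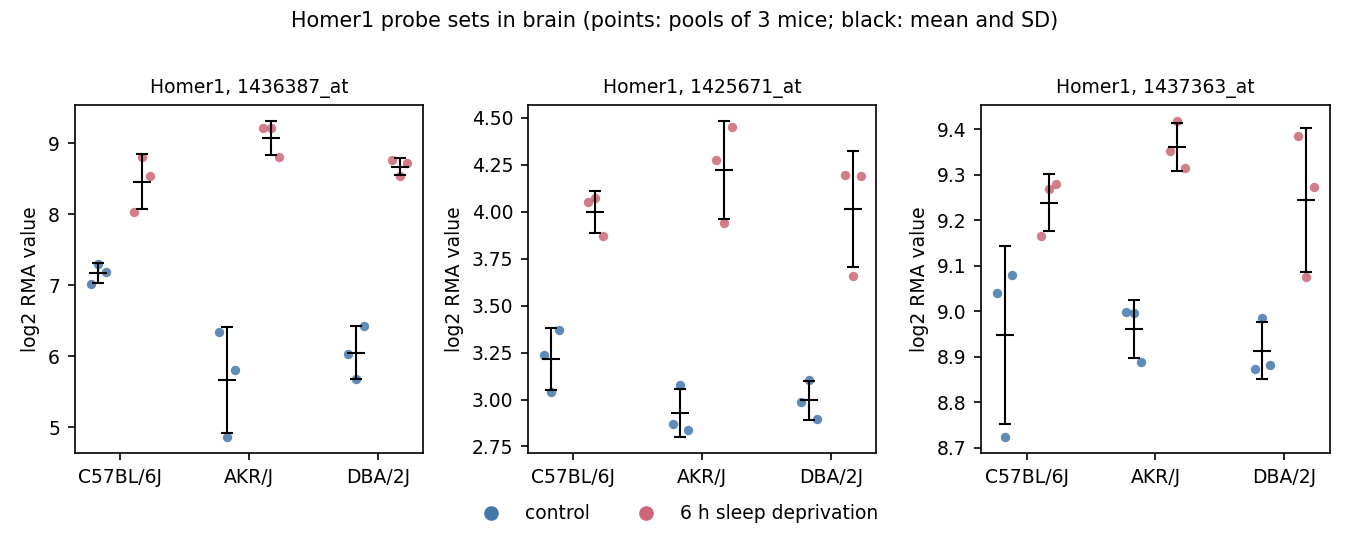
Log2 RMA expression in brain of 3 Homer1 probe sets by strain, for controls and after 6 h of sleep deprivation. Points are pools of 3 mice and black marks are group means with SD (n = 3); the probe set in the first panel shows a mean change of 2.44, that in the second 1.03 and that in the third 0.34.

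Activity-regulated genes rose as a group in brain. Of 30 measured, 13 rose and 0 fell over all genes tested, and 17 rose and 3 fell adjusted over the list alone. Besides Fosl2, the growth factor gene Bdnf rose by 0.78 ± 0.10, the transcription factor Egr3 by 0.78, and the cytoskeletal synaptic gene Arc by 0.67 ± 0.09. Egr1 (0.45 ± 0.06, adjusted p = 4.203e-04) and Fos (0.50 ± 0.12, adjusted p = 0.0363) also rose; Fos gave 0.44 in C57BL/6J, 1.26 in AKR/J and -0.22 in DBA/2J and did not pass under 18 of 33 alternatives. Arc, Egr3 and Egr1 did not pass with AKR/J left out (adjusted p = 0.0982, 0.2793 and 0.2918). Ptgs2 (0.18 ± 0.09, adjusted p = 0.4051) and Nptx2 (0.40 ± 0.10, adjusted p = 0.0636) did not pass, although Nptx2 did without the 5 doubted brain arrays (0.58, adjusted p = 0.0023). Nr4a3 gave 0.09 on its representative probe set (adjusted p = 0.8773) and rose on another (0.77 ± 0.09, adjusted p = 1.778e-04), and Btg2 gave -0.11 and fell on another (-0.32). By camera the list had an adjusted p of 8.228e-16, and an adjusted p of 0.0163 with an estimated correlation. Within strains, 10 of its genes passed in AKR/J, 1 in DBA/2J and 0 in C57BL/6J, with list medians of 0.40, 0.13 and 0.21. Signal of the pituitary hormone gene Gh also differed between conditions in AKR/J, at 4.68 to 5.18 on controls and 9.83 to 11.41 on sleep-deprived arrays. With AKR/J left out the list median was 0.15 and the list still passed by camera with the preset correlation.

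Chaperones of both compartments rose in brain. Of 21 measured heat shock genes, 18 rose and 0 fell, and 21 rose adjusted over the list alone, among them Hspa1b, Hspb1 (0.95), Chordc1 (0.70) and Hsph1 (0.55). Of 22 ER chaperone genes, 14 rose and 0 fell, and 16 rose adjusted over the list alone, with Hspa5, Creld2 (0.96), Sdf2l1 (0.95) and Manf (0.91) changing most. Genes induced by glucocorticoids rose too, 6 of 19 with 0 falls, or 9 adjusted over the list alone. These were the cell cycle inhibitor Cdkn1a (0.84 ± 0.08), the kinase Sgk1 (0.79 ± 0.11), Tsc22d3 (0.54, not with AKR/J left out, adjusted p = 0.1670), Zbtb16 (0.36, not without the AKR/J controls of conflicting label, adjusted p = 0.0644), Errfi1 and Nfkbia, while the chaperone gene Fkbp5 gave 0.26 ± 0.08 on its representative probe set (adjusted p = 0.1514; 0.39 and 0.0079 without the 5 doubted arrays) and rose on another (0.36 ± 0.07, adjusted p = 0.0092). Camera's adjusted p was 7.576e-39 for heat shock, 6.238e-36 for ER chaperones and 9.563e-14 for glucocorticoid targets. With an estimated correlation the adjusted p was 0.0053, 0.0029 and 0.0163. In C57BL/6J, AKR/J and DBA/2J alone, 0, 7 and 4 heat shock genes, 1, 11 and 6 ER chaperone genes and 2, 1 and 1 glucocorticoid targets passed.

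Clock genes did not shift in 1 direction as a group in brain, which is what camera tests. Fry's test for changes in either direction, which does not compare a list with other genes, gave an unadjusted p of 7.380e-15. Of 18 measured, 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, and camera's adjusted p was 0.9510. Dbp and Ciart (-0.45 ± 0.08, not with AKR/J left out, adjusted p = 0.1365) fell, and Arntl (0.32) and Bhlhe40 (0.30) rose. Npas2 gave 0.13 on its representative probe set (adjusted p = 0.7372) and rose on another (0.32 ± 0.06, adjusted p = 0.0126). Nfil3 gave 0.36 (adjusted p = 0.1115), Per1 0.18 ± 0.09 (adjusted p = 0.4187) and Per2 0.34 ± 0.13 (adjusted p = 0.2746). Without the 5 doubted arrays Per1 (0.33, adjusted p = 0.0335) and Per2 (0.65, adjusted p = 3.557e-04) passed.

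Metabolic lists moved little in brain. Of 17 genes of cholesterol synthesis 1 fell (Dhcr7, -0.24, not past the threshold under 22 of 33 alternatives) and 0 rose, or 4 fell and 1 rose adjusted over the list alone, while Insig1 gave -0.60 (adjusted p = 0.1408). Lanosterol synthase (Lss) gave -0.11 on its representative probe set (adjusted p = 0.4744) and fell on another (-0.60 ± 0.09, adjusted p = 0.0024). Camera's adjusted p of 0.0085 for the list became an adjusted p of 0.5788 with an estimated correlation. In fatty acid synthesis, 1 of 17 fell, the regulator Srebf1 (-0.29, adjusted p = 0.0030, and 0.0519 with AKR/J left out), or 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.6440). None of 20 genes of fatty acid oxidation passed over all genes or adjusted over the list alone (Fgf21 0.23, camera adjusted p = 0.8315; list median -0.01 and mean 0.01). In gluconeogenesis 1 of 20 rose, Gpt2 (0.35), also adjusted over the list alone (camera adjusted p = 0.5357), and it did not pass under 19 alternatives. In glycogen metabolism 2 of 19 rose, Ppp1r3g (0.31) and Ppp1r3c (0.26), or 2 with 1 fall adjusted over the list alone (camera adjusted p = 0.5048); these calls did not hold under 21 and 19 alternatives. Interferon-stimulated genes had 0 of 16 calls, or 5 lower adjusted over the list alone, with Oasl2 at -0.48 (adjusted p = 0.2312) and Ifit3 at -0.35; camera's adjusted p of 0.0015 became an adjusted p of 0.4710 with an estimated correlation.

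Neurotransmission lists and brain cell type markers stayed mostly below the threshold, with few exceptions. Of 19 glutamate receptor and scaffold genes, Homer1 alone passed by representative probe set, over all genes and adjusted over the list alone (camera adjusted p = 0.5048), and Camk2a gave -0.30 (adjusted p = 0.1524). On other probe sets Homer2 rose (0.27 ± 0.05, adjusted p = 0.0123) and Gria2 fell (-0.28 ± 0.07, adjusted p = 0.0374). None of 13 GABA genes passed either way (Gabrg1 -0.20, camera adjusted p = 0.2455). Of 19 neuropeptide genes, neurotensin (Nts) rose by 0.34 ± 0.07, also adjusted over the list alone but not with AKR/J left out (adjusted p = 0.5907), and Pomc gave 0.35 (adjusted p = 0.8553); camera's adjusted p was 0.0187, and the adjusted p = 0.4710 with an estimated correlation. Among 11 oligodendrocyte markers Opalin and Aspa (-0.54 ± 0.07), which breaks down N-acetylaspartate, fell, or 5 fell and 1 rose adjusted over the list alone, and Mog gave -0.33 (adjusted p = 0.0557). Camera's adjusted p for them, 0.0032, became an adjusted p of 0.4710 with an estimated correlation and was 0.0609 without the doubted arrays. On probe sets other than the representative, which did not pass, Mbp (0.29 ± 0.05) and Ermn (0.33 ± 0.07) rose and Cnp (-0.22 ± 0.05) fell. Of 12 astrocyte markers Gjb6 rose (0.31), also adjusted over the list alone (camera adjusted p = 0.9900), and did not pass under 20 of 33 alternatives. Tfrc was the 1 of 7 red blood cell genes to fall, also adjusted over the list alone, with Alas2 at -0.47 (adjusted p = 0.2577); camera gave 0.0348, and the adjusted p = 0.1209 with an estimated correlation. No marker of neurons (11, Nefm 0.14, camera adjusted p = 0.7298), microglia (11, Aif1 -0.23, 0.7729), endothelium (11, Slco1c1 0.23, 0.9900), choroid plexus (13, Sostdc1 -0.20, 0.9900), hepatocytes (9, Hpd 0.06, 0.6440) or lymphocytes (10, Ptprc -0.22, 0.7729) passed over all genes by representative probe set. Adjusted over the list alone, 1 microglial marker fell and 1 endothelial marker rose. The lymphocyte marker Ighm fell on another probe set (-0.28 ± 0.06, adjusted p = 0.0195). None of 9 pituitary genes passed either way (camera adjusted p = 0.5048), with growth hormone (Gh) at 1.30 ± 0.79 (adjusted p = 0.5844) and log2 levels from 4.24 to 12.87 over brain arrays. Jph3, a junctional membrane gene, gave -0.06 ± 0.05 (adjusted p = 0.6790).

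**Figure D3:**
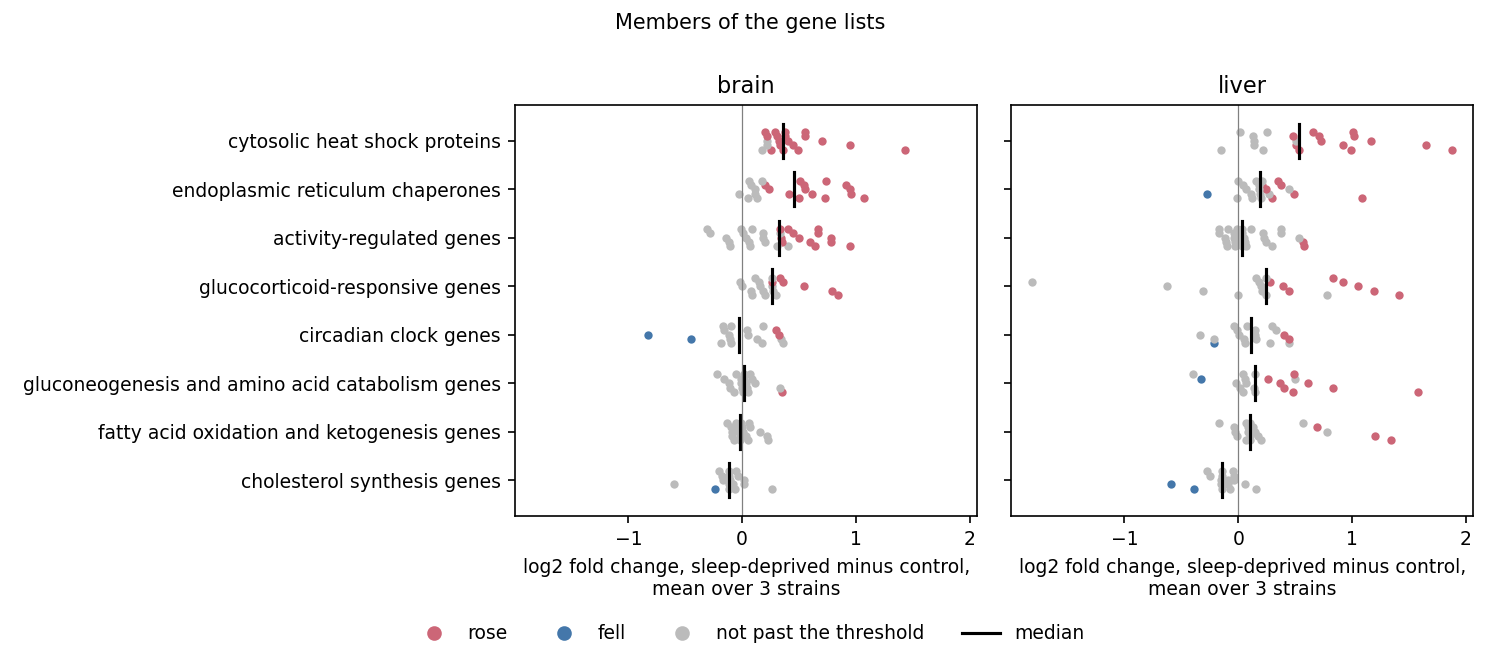
Log2 changes after sleep deprivation, averaged over strains, of the members of 8 gene lists in brain and liver. Each point is a gene, coloured by whether it rose, fell or did not pass the threshold, and bars are list medians, such as 0.36 in brain and 0.53 in liver for heat shock genes.

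Within single strains, the brain effect was asked of each strain alone. In C57BL/6J, Gm19439 (1.52 ± 0.18), Sgk1 (1.30 ± 0.18), Cdkn1a (0.86 ± 0.14), Hspa5 (0.81 ± 0.08) and Banp (0.48 ± 0.08) rose and Cirbp (-1.02 ± 0.14), Opalin, Dbp, Tfrc and Ranbp3l (-0.57 ± 0.09) fell. In AKR/J, Hspa1b (1.74 ± 0.26), Fosl2 (1.52 ± 0.22), Hspa5 (1.37 ± 0.08), Egr3 (1.31 ± 0.19) and Egr2 (1.30 ± 0.20) rose most and Cirbp (-1.40 ± 0.14), Dbp, Opalin, Tfrc and Tnik (-0.79 ± 0.14) fell most. In DBA/2J, Hspa1b (1.63 ± 0.26), Bdnf (1.08 ± 0.18), P4ha1, Hspb1 and Dio2 (each 1.04 to 1.05) led the rises and Cirbp (-1.48 ± 0.14), Opalin, Dbp, Gbp3 (-0.67 ± 0.12) and Sytl2 (-0.66 ± 0.10) the falls. All probe sets passed for 0 of 6 named genes with several in C57BL/6J, 3 of 9 in AKR/J and 3 of 7 in DBA/2J. None was called in the opposite direction. Limma called 17 probe sets in C57BL/6J (9 higher, 8 lower), 135 in AKR/J (87 and 48) and 47 in DBA/2J (32 and 15). In AKR/J the pituitary hormone gene Gh read 4.68 to 5.18 on controls and 9.83 to 11.41 on sleep-deprived arrays. Whatever caused this cannot be told apart from sleep deprivation in AKR/J, and whether it affected other calls was not tested. Between AKR/J and DBA/2J, 30 probe sets were higher and 7 lower in both, where independent lists would share 0.06 and 0.02; C57BL/6J shared 5 higher and 5 lower with AKR/J (0.02 and 0.01 for independent lists) and 3 and 6 with DBA/2J (0.01 and 0.00). Each strain's sleep-deprived group held 1 array of narrow spread, and without these arrays the counts were 45, 337 and 101. Without the 2 AKR/J controls of conflicting label limma called 7 in AKR/J, and Hspa1b, Fosl2, Egr3, Egr2, Dbp, Tfrc and Tnik did not pass there (adjusted p = 0.6602, 0.5209, 0.3842, 0.5051, 0.0903, 0.0998 and 0.6662). The counts also moved with single arrays, to between 3 and 14, 49 and 113, and 23 and 41, and Banp, Cdkn1a, Tfrc, Ranbp3l and Dbp in C57BL/6J did not pass under 11 to 14 of 20 alternatives, nor did Hspa1b in DBA/2J under 8 and Tnik in AKR/J under 7. Gbp3 in DBA/2J did not pass under 11 of 19 alternatives and Egr2 in AKR/J under 5, while of 20 alternatives Bdnf in DBA/2J did not pass under 6 and Sgk1 and Cirbp in C57BL/6J under 5 each.

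Whether the brain response differed between strains was tested directly. No probe set passed limma's interaction test, with 1005 of 45037 at an unadjusted p under 0.05 and a smallest adjusted p of 0.5872. Those 1005 are fewer than the share of 0.05 that chance alone would give, so the test was conservative here, for a cause that was not tested. Its 0 calls do not show that the strains responded alike. With array quality weights 15 passed. Hspa5, Cirbp, Fosl2, Egr3, Sgk1 and Gm19439 had an interaction adjusted p of 1.0000. The calls made in single strains are thus no measured differences between strains.

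The same question was asked of the liver. Cytosolic chaperones led the rises, with Hsph1 up 3.68-fold (1.88 ± 0.08, adjusted p = 1.557e-10) and Hspa1b 3.13-fold (1.65 ± 0.27). They were followed by Igfbp1 (1.58 ± 0.26), a binding protein of insulin-like growth factors, and the matrix protein gene Ccn2 (1.49 ± 0.15). Lipid and sugar metabolism contributed the lipid transporter Mfsd2a (1.42 ± 0.18), the phosphatidate phosphatase Lpin1 (1.41 ± 0.11), the acyl-CoA thioesterase Acot1 (1.34 ± 0.12) and the glycolytic regulator Pfkfb3 (1.29 ± 0.14), and Zbtb16 (1.41 ± 0.12) and Rgs16 (1.21 ± 0.24) completed the 10 largest. Cirbp fell here as well, to a level 2.94-fold lower (-1.56 ± 0.09, adjusted p = 2.411e-09), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 0.83 ± 0.14. Nrep (-0.92 ± 0.21), BC023105 (-0.87 ± 0.21), Calhm6 (-0.86 ± 0.18), Wdr6, Arl2bp, the glucuronosyltransferase Ugt2b35, Osgin1 and Gdap10 (-0.75 ± 0.16) were the other large falls. BC023105 gave -2.26 in DBA/2J, -0.31 in C57BL/6J and -0.03 in AKR/J. Of the 20 genes 10 had other probe sets, and a probe set of Cyp7a1 alone did not pass. Limma called 1622 probe sets, 1079 higher and 543 lower, and 887 genes, 540 higher and 347 lower. With AKR/J left out it called 783, and without the 2 AKR/J controls of conflicting label 982. Gdap10 and Nrep did not pass with AKR/J left out (adjusted p = 0.2874 and 0.0570), and BC023105 did not pass under 3 of 30 alternatives (highest adjusted p = 0.1314), among them that without the AKR/J controls of conflicting label.

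In liver, 13 of 21 heat shock genes rose and 0 fell, or 17 and 1 adjusted over the list alone, with Hspb1 at 1.17 and Hsp90aa1 at 1.02 next to Hsph1 and Hspa1b (camera adjusted p = 2.331e-31; adjusted p = 8.530e-04 with an estimated correlation). Glucocorticoid-induced genes rose, 8 of 19 with 0 falls, or 11 adjusted over the list alone. They included Zbtb16, Tsc22d3 (1.19), the growth inhibitor Ddit4 (1.05), Fkbp5 (0.92 ± 0.12), the tyrosine-degrading enzyme Tat (0.83) and Sgk1 (0.39 ± 0.09, not without the AKR/J controls of conflicting label, adjusted p = 0.1168), while Lcn2, also an acute-phase gene, gave -1.81 ± 0.79 (adjusted p = 0.2668). The list had a camera adjusted p of 1.070e-11, and an adjusted p = 0.0038 with an estimated correlation. Of 22 ER chaperone genes 7 rose, led by Creld2 (1.09 ± 0.07), Herpud1 (0.49) and Hspa5 (0.38 ± 0.06), and the transcription factor Atf4 fell (-0.27), or 16 and 1 adjusted over the list alone; camera's adjusted p of 3.304e-11 became an adjusted p of 0.0548 with an estimated correlation. The median of this ER chaperone list was 0.37 in AKR/J, 0.08 in C57BL/6J and 0.02 in DBA/2J. In these strains alone 9, 2 and 1 of its genes were called, so the rise was mostly seen in AKR/J. Hspa5 in liver did not pass with AKR/J left out (0.13, adjusted p = 0.4509). Activity-regulated genes had 2 rises of 30, Jun (0.58 ± 0.10, not with AKR/J left out, adjusted p = 0.0586) and Dusp6 (0.57), or 5 rises and 2 falls adjusted over the list alone, while Egr1 gave 0.53 ± 0.24 (adjusted p = 0.2859) and Fos 0.23 ± 0.09 (adjusted p = 0.2108). Camera's adjusted p for them was 0.0368, the adjusted p = 0.3850 with an estimated correlation, and 0.0565 without DBA/2J control array 1. Of 18 clock genes Per1 (0.45 ± 0.09, not without the AKR/J controls of conflicting label, adjusted p = 0.0575) and Cry1 (0.40) rose and Bhlhe41 (-0.21) fell, or 7 and 2 adjusted over the list alone, while Nfil3 gave 0.45 (adjusted p = 0.0988), Per2 0.28 (adjusted p = 0.2114) and Dbp -0.34 ± 0.11 (adjusted p = 0.1171); camera's adjusted p of 0.0075 became an adjusted p of 0.1286 with an estimated correlation. On probe sets other than the representative, which did not pass, Hspa4 (0.52 ± 0.05), Clock (0.40 ± 0.06) and Nfkbia (0.32 to 0.45) rose, and Per3 fell (-0.27 ± 0.07). Dnaja4 (0.45), Dnajc3 (0.22 and 0.33), Edem1 (0.21), Syvn1 (0.47), Cebpb (0.60), Gpt2 (0.26) and Ocln (0.37) also rose on such probe sets. Arc (-0.10), Bdnf (0.03), Ptgs2 (-0.04), Nptx2 (-0.17) and Jph3 (0.01) did not pass in liver.

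Genes of fasting metabolism and lipid synthesis both contained rises in liver. In gluconeogenesis and amino acid breakdown, 8 of 20 rose and 1 fell, or 10 and 1 adjusted over the list alone, with Igfbp1, Tat, glucose-6-phosphatase (G6pc, 0.61) and phosphoenolpyruvate carboxykinase (Pck1, 0.49) rising and the histidine-degrading enzyme Hal falling (-0.33). By camera this list had an adjusted p of 8.480e-08, and an adjusted p = 0.0520 with an estimated correlation. In fatty acid oxidation 3 of 20 rose, or 4 adjusted over the list alone, namely Acot1, the lipase inhibitor Angptl4 (1.20) and the lipid droplet protein Plin5 (0.69), and Pdk4 gave 0.78 (adjusted p = 0.3098); camera's adjusted p of 1.842e-07 became an adjusted p of 0.1286 with an estimated correlation. In fatty acid synthesis 5 of 17 rose and 1 fell, or 10 and 1 adjusted over the list alone, with the elongase Elovl6 (0.52), the regulator Mlxipl (0.43) and acetyl-CoA carboxylase Acaca (0.41) rising and Srebf1 falling (-0.56). Mlxipl and Srebf1 did not pass with AKR/J left out (adjusted p = 0.0941 and 0.1366). Tested with camera, the list had an adjusted p of 1.114e-05, and an adjusted p = 0.1656 with an estimated correlation. In cholesterol synthesis Hmgcs1 (-0.59) and Msmo1 (-0.39) fell, 2 of 17, or 3 adjusted over the list alone (camera adjusted p = 0.0086; adjusted p = 0.4723 with an estimated correlation). Lss gave -0.04 on its representative probe set (adjusted p = 0.9097) and fell on another (-0.43 ± 0.11, adjusted p = 0.0451). Hmgcs1 and Msmo1 did not pass under 4 of 30 alternatives, among them AKR/J left out (adjusted p = 0.1379 and 0.1011). In bile acid metabolism 3 of 16 fell, Cyp7a1, Abcg5 (-0.34) and Hsd3b7 (-0.24), and the repressor Nr0b2 rose (0.56), or 4 and 1 adjusted over the list alone (camera adjusted p = 0.2128). With AKR/J left out, Abcg5 gave -0.12 (adjusted p = 0.5366) and Nr0b2 0.54 (adjusted p = 0.0651), and neither passed. Glycogen metabolism had 1 rise of 19, Ppp1r3b (0.76 ± 0.12), or 2 adjusted over the list alone (camera adjusted p = 0.3268).

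Of 21 xenobiotic metabolism genes 3 rose, also adjusted over the list alone, the cytochrome Cyp2b10 (1.00 ± 0.27), the xenobiotic receptor Nr1i2 (0.56) and Gstm2 (0.30); Cyp2b10 and Gstm2 did not pass under 17 and 16 of 30 alternatives. In the camera test this list had an adjusted p of 0.0418, the adjusted p = 0.3996 with an estimated correlation, and 0.1826 without DBA/2J control array 1. Acute-phase genes had 1 fall of 21, Apcs (-0.72), or 8 falls and 2 rises adjusted over the list alone, while Orm2 gave -1.92 ± 0.59 (adjusted p = 0.0880), Saa2 -1.77 ± 0.75 (adjusted p = 0.2487) and Saa1 -1.26; camera's adjusted p of 0.0086 became an adjusted p of 0.4723 with an estimated correlation. Of 10 male-biased liver genes Hsd3b5 (-0.53, not with AKR/J left out, adjusted p = 0.0857) and Nudt7 (-0.36) fell and the elongase Elovl3 rose (0.44, not under 13 of 30 alternatives), or 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.1544). None of 16 interferon-stimulated genes passed either way (Gbp3 -0.36, adjusted p = 0.2666; camera adjusted p = 0.0177, and adjusted p = 0.4723 with an estimated correlation). Of 11 endothelial markers 3 rose and 8 did not pass, or 5 rose adjusted over the list alone, and those that rose were the growth factor receptor Flt1 (0.45 ± 0.06), Pecam1 (0.42) and Tek (0.36). Camera's adjusted p for this list, 1.466e-04, became an adjusted p of 0.1151 with an estimated correlation. With AKR/J left out Pecam1 (0.31, adjusted p = 0.1190) and Tek (0.26, adjusted p = 0.1601) did not pass, and the list median was -0.01 in C57BL/6J, 0.22 in AKR/J and 0.18 in DBA/2J. Stellate cell markers had 0 of 11 calls, or 5 rises adjusted over the list alone, with Col3a1 at 0.34 (adjusted p = 0.0534) and Acta2 at 0.33. For stellate cells camera's adjusted p of 3.092e-04 became an adjusted p of 0.1121 with an estimated correlation. Of 12 Kupffer cell markers Cd163 rose (0.58 ± 0.13), also adjusted over the list alone (camera adjusted p = 0.4938), and of 10 lymphocyte markers Cd79a fell (-0.29), or 2 adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.1028 with an estimated correlation). Neither Cd163 nor Cd79a passed with AKR/J left out (adjusted p = 0.0756 and 0.0741). No marker of hepatocytes (9, Hpd 0.13, camera adjusted p = 0.1696), red blood cells (7, Tfrc 0.11, 0.7178), bile ducts (6, Krt19 0.34, 0.3081) or exocrine pancreas (10, Cela2a -0.22, 0.1930) passed over all genes, and 1 pancreas marker fell adjusted over the list alone.

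In the livers of single strains, C57BL/6J showed its largest rises for Ccn2 (2.52 ± 0.27), Mfsd2a (2.32 ± 0.32), Igfbp1, Lpin1 (2.27 ± 0.19) and Zbtb16, and its largest falls for Cirbp (-1.49 ± 0.15), Clec2h, Cyp7a1 (-1.40 ± 0.25), Cyp2u1 and Arrdc3. In AKR/J, chaperones made up the largest rises, namely Creld2 (2.33 ± 0.13), Hsph1 (2.30 ± 0.14), Hspa1b (2.02 ± 0.46), Hspb1 (1.87 ± 0.21) and Hsp90aa1 (1.69 ± 0.10), and Cirbp (-1.87 ± 0.15), the peroxisomal transporter Abcd2 (-1.60 ± 0.25), Gdap10, Wdr6 and Rdh9 fell most. In DBA/2J, Hsph1 (2.09 ± 0.14), Zbtb16, Acot1, Pfkfb3 and Hspb1 rose and BC023105 (-2.26 ± 0.36), Crybb3, the nucleic acid sensor Zbp1 (-1.39 ± 0.26), Calhm6 and Cirbp (-1.31 ± 0.15) fell. All probe sets passed for 2 of 5 named genes with several in C57BL/6J, 3 of 6 in AKR/J and 3 of 5 in DBA/2J. Limma called 277 probe sets in C57BL/6J (236 higher, 41 lower), 320 in AKR/J (203 and 117) and 283 in DBA/2J (206 and 77). Shared calls numbered 50 higher and 12 lower for C57BL/6J and AKR/J (1.06 and 0.11 for independent lists), 71 and 10 for C57BL/6J and DBA/2J (1.08 and 0.07) and 66 and 14 for AKR/J and DBA/2J (0.93 and 0.20). Without the 2 AKR/J controls of conflicting label the count in AKR/J was 58, and Hspa1b, Wdr6 and Rdh9 did not pass there (adjusted p = 0.3588, 0.1156 and 0.1107). Single arrays moved these counts to between 108 and 263, 149 and 289, and 71 and 459. Hspa1b in AKR/J and Arrdc3, Pfkfb3 and Calhm6 in the strains named did not pass under 9, 5, 7 and 12 of 17 alternatives, nor did Crybb3 in DBA/2J under 7 and Igfbp1 in C57BL/6J under 5.

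The liver response differed between strains for a small set of genes. Creld2, an ER stress gene, gave a log2 change of 2.33 in AKR/J, 0.58 in C57BL/6J and 0.34 in DBA/2J (interaction adjusted p = 1.077e-04), and the cytosolic chaperone Hsp90aa1 gave 1.69, 0.28 and 1.07 (adjusted p = 8.174e-04). In the same order, Hsp90aa1 read 9.29 to 9.67, 10.55 to 10.64 and 9.81 to 9.88 on controls. After sleep deprivation it read 11.05 to 11.30, 10.78 to 10.93 and 10.80 to 10.98. Creld2 read 7.62 to 7.68, 8.76 to 8.97 and 7.99 to 8.53 on controls. Both differences thus lie partly in the controls, which read lowest in AKR/J. Manf, another ER stress gene, followed Creld2 with 1.11, -0.05 and -0.02 (adjusted p = 0.0337). Rrm2, a ribonucleotide reductase subunit, gave 1.48 in C57BL/6J, 0.44 in AKR/J and -0.22 in DBA/2J (adjusted p = 0.0118), and Rnf186 gave -0.77, -0.10 and 0.16 (adjusted p = 0.0402). Gm7969 also passed (0.71, -0.23 and -0.15, adjusted p = 0.0114), but it read 2.42 to 2.88 on the arrays of AKR/J and DBA/2J, near the lowest value of all, 2.12, against 6.47 to 7.41 in C57BL/6J. Its response could thus not be measured in these strains, and its call is no measured difference in response. Rrm2 was dim in the same strains, with group means of 4.12 to 4.56 against 5.28 and 6.76 in C57BL/6J, so the size of its difference is uncertain. Limma's interaction test called 15 probe sets, and 6 genes by representative probe set, with 3077 probe sets at an unadjusted p under 0.05. Hspa5 had a like pattern of 0.88 in AKR/J, 0.12 in C57BL/6J and 0.14 in DBA/2J and did not pass (adjusted p = 0.0519), nor did Hsph1 (adjusted p = 0.1825) or Lpin1 (adjusted p = 0.1546). Without the 2 AKR/J controls of conflicting label Manf (adjusted p = 0.2766) and Rnf186 (adjusted p = 0.0542) did not pass, and without AKR/J sleep-deprived array 1, on which the 18S rRNA control was raised, their adjusted p was 0.0761 and 0.0631; over 28 alternatives they did not pass in 12 and 17. Rrm2 and Gm7969 did not pass without C57BL/6J control 2 (adjusted p = 0.0542 for each), nor did Gm7969 without C57BL/6J control 1. The count moved to 9 without C57BL/6J control 2 or DBA/2J sleep-deprived array 3, to 25 without C57BL/6J sleep-deprived array 2 and to 24 without DBA/2J control 3.

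**Figure D4:**
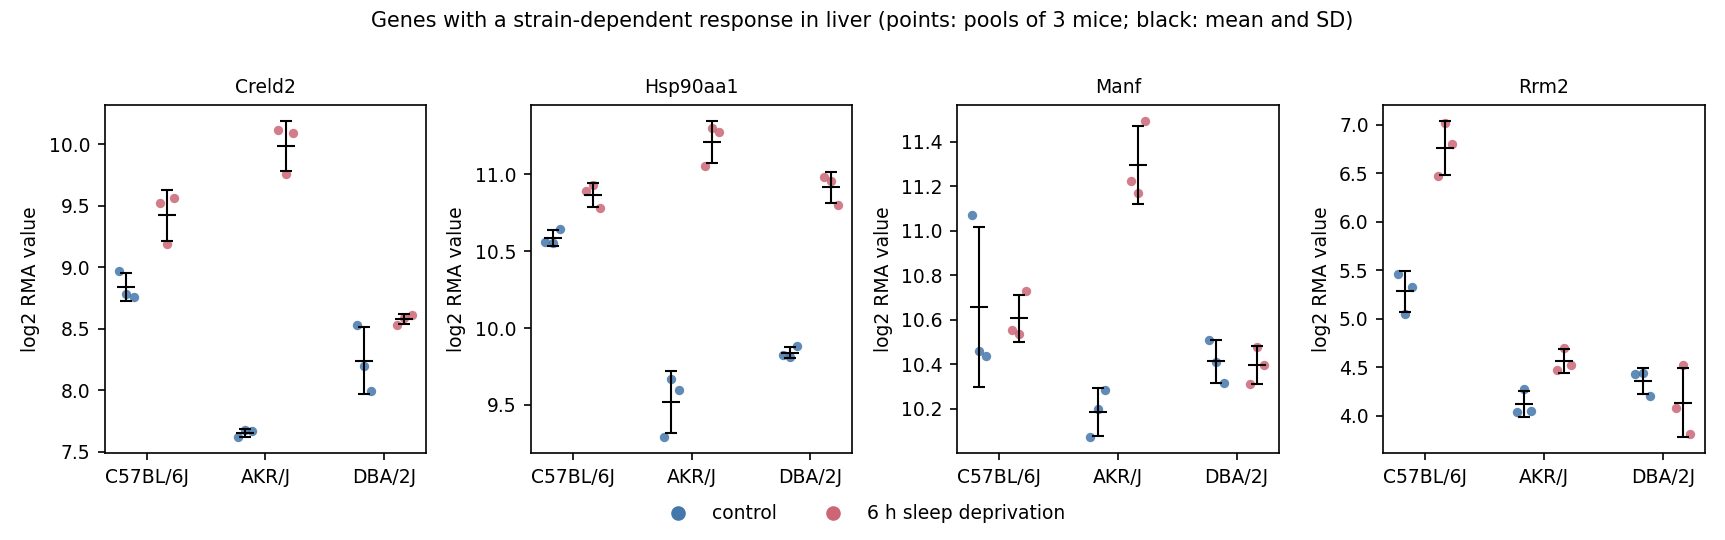
Log2 RMA expression in liver of Creld2, Hsp90aa1, Manf and Rrm2 by strain, for controls and after 6 h of sleep deprivation. Points are pools of 3 mice and black marks are group means with SD (n = 3); the change of Creld2 is 2.33 in AKR/J against 0.58 and 0.34 in the other strains.

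Brain and liver responses were compared through their changes, since levels were not comparable between the tissues. Hsph1 rose in both and had a change larger by 1.33 ± 0.10 in liver (0.55 in brain, 1.88 in liver; adjusted p of the difference = 1.012e-09). The cytosolic chaperones Hsp90aa1 and Hspa8 rose in liver with changes larger there by 0.89 ± 0.08 and 0.80 ± 0.08, while the same probe sets gave 0.12 and 0.20 in brain, which did not pass. Another probe set of Hspa8 rose in brain too (0.33, adjusted p = 2.734e-04). Hspa5 went the other way, with a change 0.69 smaller in liver (-0.69 ± 0.07, adjusted p = 4.712e-07; 1.07 in brain, 0.38 in liver). Lpin1 rose in liver (1.41) and not in brain (-0.04), a difference of 1.45 ± 0.13, and Tedc2 (1.01 ± 0.08), Etfbkmt (1.19 ± 0.13) and Fbxo31 (0.81 ± 0.09) likewise had larger changes in liver. Opalin fell in brain (-0.95) and gave -0.07 in liver, and Ugt2b35 fell in liver (-0.84) and gave -0.04 in brain. The signal of Opalin in liver and of Ugt2b35, Lpin1, Tedc2, Etfbkmt and Fbxo31 in brain is not given here. Low signal there thus cannot be told apart from a lack of response. Limma called 623 probe sets with a different change, 458 with a higher value in liver and 165 with a lower one, or 371 genes (274 and 97). The 10 genes passed under each of the 50 alternatives run. The count was 202 with AKR/J left out and 301 without the AKR/J controls of conflicting label. Of the probe sets called in each tissue, 82 were higher in both and 51 lower in both, where independent lists would share 7.43 and 5.64, and 7 were called in opposite directions. Whether the pools of both tissues came from the same mice is not given in the sources used here, and shared mice would make these lists, and the tissues in the test of the difference, not independent.

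Strain differences were measured among controls, brain first. Against C57BL/6J, AKR/J brains had higher signal for Tmem87a (2.82 ± 0.11), Wdfy1, Lsm12, the phospholipase gene Pla2g4e and the potassium channel gene Kcnj9 (1.83 ± 0.12) and lower signal for Gh (-6.26 ± 1.37), Rpgrip1 (-4.01 ± 0.19), Pttg1 (-3.57 ± 0.43), Ogfrl1 and Soga3. DBA/2J brains had higher signal than C57BL/6J for Cap1 (3.96 ± 0.13), Stab2 (2.92 ± 0.18), Tmem87a, Rbm45 and Wdfy1 and lower signal for the noncoding RNA Snhg14 (-4.60 ± 0.26), Pttg1, Tmem267 (-3.27 ± 0.22), Pdxdc1 and Rpgrip1. Against AKR/J, DBA/2J brains had higher signal for the pituitary hormone genes Gh (6.48 ± 1.37), Prl (4.08 ± 0.97) and Cga (3.87 ± 0.88) and for Cap1 and Pisd-ps3, and lower signal for Snhg14, Tmem267, Pdxdc1, Krt12 and Acer3. Limma called 901 probe sets between AKR/J and C57BL/6J (416 higher, 485 lower), 854 between DBA/2J and C57BL/6J (361 and 493) and 714 between DBA/2J and AKR/J (345 and 369). These comparisons share control arrays. Averaged over control and sleep-deprived arrays, the counts were 2053, 1884 and 1483. Without AKR/J control 3, 555 probe sets differed between AKR/J and C57BL/6J. Gh also varied within strains, at 4.68 to 5.18 on AKR/J controls, 9.83 to 11.41 on AKR/J sleep-deprived arrays and 4.24 on C57BL/6J sleep-deprived array 3. Whether each brain was taken with its pituitary is not given in the sources used here, so the values of Gh, Prl and Cga are not shown to be strain differences. The cause of the low Gh on the AKR/J controls cannot be told apart from strain in the comparisons with AKR/J. Whether it affected other calls there was not tested. Of 21 alternatives, Gh did not pass under 11 and 9, Prl under 10 and Cga under 9, and 1 probe set each of Kcnj9, Ogfrl1 and Pdxdc1 was called in the direction opposite to the value given. All probe sets passed in the same direction for 2 of 8 named genes with several in AKR/J against C57BL/6J. This held for 1 of 6 in DBA/2J against C57BL/6J and 4 of 7 in DBA/2J against AKR/J.

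Among control livers, the largest strain differences included drug-metabolising enzymes and immune genes. AKR/J livers had lower signal than C57BL/6J for Ugt3a2 (-6.99 ± 0.22), the cytochromes Cyp2c37 (-6.72 ± 0.29) and Cyp4a14 (-4.67 ± 0.83), the histocompatibility gene H2-K1 (-4.47 ± 0.14) and the pantetheinase Vnn1 (-4.37 ± 0.25), and higher signal for Abhd1 (3.62 ± 0.11), Cyp2c39 (3.55 ± 0.19), Pik3ap1, Cplane1 and Cyp46a1. DBA/2J livers had higher signal than C57BL/6J for Obp2a (7.34 ± 0.31), an odorant-binding protein gene, Ifi202b (4.83 ± 0.24), Pik3ap1, Rassf4 and Cap1 and lower signal for Nlrp12 (-5.19 ± 0.22), Nnmt, Gm7969, Cyp4a14 and Mndal (-3.63 ± 0.11). Against AKR/J, DBA/2J livers had higher signal for Ugt3a2 (6.68 ± 0.22), Obp2a, Cyp2c37, H2-D1 (4.26 ± 0.22) and Vnn1 and lower signal for Nlrp12, Abhd1 (-3.94 ± 0.11), Mme, Cplane1 and Pdxdc1. Limma called 2293 probe sets between AKR/J and C57BL/6J (1362 higher, 931 lower), 2508 between DBA/2J and C57BL/6J (1505 and 1003) and 1898 between DBA/2J and AKR/J (1037 and 861), and 5505, 5514 and 3854 when averaged over both conditions. Without AKR/J control 2, 1425 differed between AKR/J and C57BL/6J. Cyp4a14 did not pass between AKR/J and C57BL/6J without the AKR/J controls of conflicting label (adjusted p = 0.0742), nor between DBA/2J and C57BL/6J under 5 of 18 alternatives. Of these calls, 290, 301 and 259 probe sets were also called in brain, with 7, 16 and 13 of them in the opposite direction; for AKR/J against C57BL/6J 148 were lower and 135 higher in both tissues, for DBA/2J against C57BL/6J 168 and 117, and for DBA/2J against AKR/J 121 and 125. Independent lists would share 7.1 to 12.6 of either direction. All probe sets passed in the same direction for 2 of 4 named genes with several in AKR/J against C57BL/6J liver. This held for 3 of 5 in DBA/2J against C57BL/6J and 2 of 5 in DBA/2J against AKR/J. Of the genes called by representative probe set that had others, 31.3% to 35.6% in liver and 24.5% to 31.1% in brain had another called in the same direction, and 1 probe set each of H2-D1 and Pdxdc1 was called in the opposite direction. Since array probes can bind transcripts with sequence variants less well, these values are differences in signal.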

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

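The tests without the 3 brain arrays of narrow spread, without the 2 brain arrays of raised 3' to 5' ratio and without DBA/2J liver control 1 were chosen only after the result was seen, and the test on probe variants, written before, was read per tissue after its values were seen.

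In liver, 15 probe sets had a response to sleep deprivation that differed between strains in limma's interaction test, and ER and cytosolic chaperones were the named genes with the largest response in AKR/J. The largest difference between strains was 1.99 on the log2 scale for Creld2, 1.41 for Hsp90aa1 and 1.16 for Manf. Creld2 and Hsp90aa1 also read lowest on the AKR/J controls, so their differences lie partly in the controls. A wrong sampling time of AKR/J controls 2 and 3, of which 1 label says ZT 0, is argued against in liver, where alone it was tested, by clock genes: the median absolute log2 difference of 11 of them between control 1 and these arrays was 0.15, below the largest such value in the other strains, 0.37. Degraded RNA on DBA/2J control 1 is argued against for Creld2 and Hsp90aa1, which passed without that array (adjusted p = 4.559e-05 and 0.0014); 6 of 6 named genes did, but Gm7969 could not be measured in every strain, and Manf and Rnf186 passed narrowly (adjusted p = 0.0477 and 0.0465). What stays open, and untested, is a difference between the strains themselves, which may be genetic, and Manf and Rnf186 rest on few arrays, with an adjusted p of 0.2766 and 0.0542 without the AKR/J controls of conflicting label.

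In brain, 60.2% of the 778 probe sets called were lower after sleep deprivation. Without the 3 sleep-deprived arrays of narrow spread, 33.5% of 1747 were lower, and the 26 other ways of leaving out 1 sleep-deprived array per strain gave 41.2% to 69.9%. Among these the share was 41.2% to 48.6% with 2 of the narrow arrays left out, 53.6% to 60.9% with 1 and 64.2% to 69.9% with 0. Lower calls numbered 468 with the 3 arrays and 586 without them, so the share fell because calls of rises increased more. The balance of calls thus moved with the number of these 3 arrays left out, but the lower calls are not shown to come from them. A dependence of the balance on these arrays is a candidate explanation found and tested on the same data. Without the 2 control arrays of raised 3' to 5' ratio the share was 54.2%, which lies between the bounds set for and against that explanation, so an effect of RNA quality stays open. No biological explanation was tested for the balance of rises and falls.

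Strain differences could also reflect sequence variants under probes designed on the C57BL/6J sequence, which would lower the signal of AKR/J and DBA/2J. In liver 40.6% (95% confidence interval 38.6 to 42.6) of the called probe sets were lower in AKR/J and 40.0% (38.1 to 41.9) in DBA/2J. Variants as the main source would give a majority of lower calls, which the main fit did not show in liver. For AKR/J this depended on the setting, as given below. The shares do not measure how many calls variants caused, since differences in expression enter them too. The intervals treat probe sets as independent, although these share the same arrays. In brain the shares were 53.8% (50.5 to 57.1) and 57.7% (54.3 to 61.1), and variants cannot be told apart from strain differences in expression, since both intervals hold the bound of 55% set for the test. Over the settings fixed in advance the shares went from 43.8% to 58.4% and from 52.7% to 60.3% in brain, and from 33.6% to 51.3% and from 31.5% to 47.2% in liver. Between DBA/2J and AKR/J the share was 51.7% in brain and 45.4% in liver, and of the probe sets called in both tissues 148 of 290 were lower in both for AKR/J against C57BL/6J, 168 of 301 (55.8%) for DBA/2J against C57BL/6J and 121 of 259 (46.7%) for DBA/2J against AKR/J. Any single probe set may still be affected, and genetic differences in expression stay open and untested.

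Other differences between groups passed a direct test. Rrm2 (1.71, of uncertain size, since it was dim in AKR/J and DBA/2J) and Rnf186 (0.93) had the other named differences between strains in liver, and a value of 0.94 for Gm7969 is no measured difference, since it read 2.42 to 2.88 in AKR/J and DBA/2J, near the lowest value of 2.12. Between the tissues, 623 probe sets differed in their response. The difference, liver minus brain, was 1.33 for Hsph1, 1.01 for Tedc2, 0.89 for Hsp90aa1, 1.45 for Lpin1, 0.80 for Hspa8, -0.69 for Hspa5, 0.88 for Opalin, -0.80 for Ugt2b35, 1.19 for Etfbkmt and 0.81 for Fbxo31. For Opalin, Ugt2b35, Lpin1, Tedc2, Etfbkmt and Fbxo31, low signal in the tissue without a called change is not told apart here from a lack of response. Among the control probe sets, which no comparison used, the 18S ribosomal RNA 5' probe set read 11.61 on AKR/J liver sleep-deprived array 1 and 5.37 to 6.45 on the other 17 liver arrays.

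Other assignments of the same arrays to groups were drawn for each count. For the mean brain effect 1 of 100 splits, the real one, gave as many calls (778 against at most 135 in the others), and the same held for the mean liver effect (1622 against 673), the liver interaction (15 against 2) and the tissue difference (623 against 87). This is the smallest share that 100 splits can give, so chance is argued against for the mean effects but not excluded. Splits for the tissue difference exchanged conditions within tissue and strain, which removes the effect of sleep deprivation itself. They thus do not test equal effects in both tissues. Those for the liver interaction moved what strain and condition left unexplained between all groups, and assume that arrays of all groups can be exchanged. For the brain interaction, with 0 calls by limma and 1005 probe sets at an unadjusted p under 0.05, 100 of 100 splits gave as many by construction, so this count says nothing about chance. The highest other split called 6618 and put 2 of the 3 arrays of narrow spread in 1 group. The next called 66 and put at most 1 of them in a group, and only 3 splits had a call. A link of these calls to the narrow arrays was not tested. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. Their real counts and highest others were 17 and 0, 135 and 0, and 47 and 1 for the brain effect in C57BL/6J, AKR/J and DBA/2J, and 277 and 5, 320 and 2, and 283 and 5 for the liver effect. For AKR/J against C57BL/6J, DBA/2J against C57BL/6J and DBA/2J against AKR/J they were 901 and 0, 854 and 0, and 714 and 0 in brain and 2293 and 0, 2508 and 1, and 1898 and 0 in liver.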

How the results depend on the processing

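The alternatives without doubted arrays were chosen after the data were seen. They left out the 3 brain arrays of narrow spread, the 2 of raised 3' to 5' ratio or all 5 and, for the liver lists and the tissue difference, DBA/2J liver control 1. All others, each array left out in turn included, were fixed in advance. Over the settings fixed in advance, values of named genes kept their direction and side of the threshold in 2787 cases, fell below it in 193, rose past it in 13 and reversed in 6; with 1 array left out the numbers were 3103, 303, 5 and 9, and without doubted arrays 341, 26, 9 and 0. Dim probe sets and small changes limit these counts, since simulated changes of 0.3 in a strain were mostly missed. Except where fewer arrays or fewer probe sets entered, the cause of a change in count was not tested. Values follow as counts of probe sets called, with the main count in the report. In the order C57BL/6J, AKR/J and DBA/2J are the effects within strains, and in the order AKR/J against C57BL/6J, DBA/2J against C57BL/6J and DBA/2J against AKR/J the strain differences.

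With array quality weights limma called 3965 for the mean brain effect, 774, 1541 and 559 within strains, 15 for the brain interaction, 3872, 2130 and 2261 for brain strain differences, 180 for DBA/2J liver and 1462 for the tissue difference. With 1 probe set per gene, which tests fewer features, it called 11 and 86 in C57BL/6J and AKR/J brain, 392, 329 and 293 for brain strain differences, 1039 for the mean liver effect, 166 in C57BL/6J liver and 1179 for DBA/2J against AKR/J liver. Median centring gave 499 for the mean brain effect and 78 in AKR/J brain, and a repeated quantile normalisation 1374 and, within strains, 45, 240 and 127. The share of lower calls went from 33.5% to 21.0% for the mean liver effect with median centring, and with quantile normalisation from 26.5% to 39.6% for the tissue difference, from 47.1% to 26.7% in C57BL/6J brain and from 40.6% to 51.3% for AKR/J against C57BL/6J liver. In DBA/2J liver it went from 27.2% to 16.6% with median centring and 37.4% with quantile normalisation. The fit on all 36 arrays gave 1250 for the mean brain effect, 205 and 102 in AKR/J and DBA/2J brain, 464 in DBA/2J liver and 68 for the liver interaction. Fits on the 2 groups alone gave 0 (1458 at an unadjusted p under 0.05 by limma), 30 and 9 within strains in brain, 182 and 39 in AKR/J and DBA/2J liver, and 1524 and 1035 for DBA/2J against C57BL/6J and AKR/J liver. A trended and robust prior gave 25 for the liver interaction. Averaged over conditions, with more arrays, strain differences numbered 2053, 1884 and 1483 in brain and 5505, 5514 and 3854 in liver.

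With AKR/J left out the counts were 85 and 783 for the mean brain and liver effects and 202 for the tissue difference. Without the AKR/J controls with a ZT 0 label, which leaves 1 array assumed to vary like the other groups, they were 300 for the mean brain effect, 10 and 7 in C57BL/6J and AKR/J brain, 259 and 271 for AKR/J against C57BL/6J and DBA/2J against AKR/J brain, 982 for the mean liver effect, 58 in AKR/J liver, 702 and 726 for the same strain differences in liver, and 301 for the tissue difference. Without the 3 arrays of narrow spread they were 1747, 45, 337, 101, 1892, 1652 and 1291 for the mean brain effect, strains and strain differences, and without all 5 doubted arrays 1866, 27, 603, 174, 1665, 1352 and 1283. Without the 2 arrays of raised ratio they were 439 for the mean brain effect and 3 in C57BL/6J. Of the 24 list calls, 6 held with an estimated correlation.

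Replicate numbers did not pair the arrays: over 45 pairs per tissue the mean correlation of same-numbered deviations was -0.004 in brain and 0.010 in liver, and 7 and 9 of 18 arrays correlated best with their own number. The replicate block gave 8 calls in C57BL/6J brain, 610 and 1578 for the mean effects and 587 for the tissue difference, and moved no other count by over 1.5 times.

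Leaving out 1 array at a time gave ranges of 479 to 807 for the mean brain effect, 3 to 14, 49 to 113 and 23 to 41 within strains, 0 to 4 for the brain interaction, 555 to 651, 594 to 711 and 510 to 545 for brain strain differences, 1209 to 1638 for the mean liver effect, 108 to 263, 149 to 289 and 71 to 459 within strains, 9 to 25 for the liver interaction, 1425 to 1841, 1749 to 2739 and 1373 to 2006 for liver strain differences and 472 to 646 for the tissue difference. Counts moved by over 1.5 times without AKR/J control 1 for the mean brain effect (479), without C57BL/6J sleep-deprived array 3 for the brain interaction (4), and without AKR/J control 3 in brain (555) or control 2 in liver (1425) for AKR/J against C57BL/6J. Within C57BL/6J brain they did so without controls 1 to 3 (3, 8 and 6) and sleep-deprived arrays 1 and 3 (9 and 8). In AKR/J brain it was controls 1 to 3 (66, 49 and 59) and sleep-deprived arrays 1 and 2 (49 and 68), and in DBA/2J brain controls 1 to 3 (27, 28 and 30) and sleep-deprived arrays 1 and 3 (28 and 23). In C57BL/6J liver it was controls 1 and 2 (155 and 163) and sleep-deprived array 3 (108), in AKR/J liver controls 1 to 3 (201, 163 and 189) and sleep-deprived arrays 1 and 2 (211 and 149), and in DBA/2J liver controls 1 and 3 (111 and 459) and sleep-deprived arrays 1 to 3 (71, 132 and 149). For the liver interaction it was C57BL/6J control 2 (9) and sleep-deprived array 2 (25) and DBA/2J control 3 (24) and sleep-deprived array 3 (9).

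Values near 0 that had not passed reversed in liver. Bdnf was -0.03 without the AKR/J controls of conflicting label and -0.02 to 0.08 with 1 array left out, and Jph3 was -0.13 with AKR/J left out and -0.03 to 0.05 with 1 array left out. Of the Homer1 probe sets, the brightest was 0.01 with AKR/J left out, another 0.07 both then and without the AKR/J controls of conflicting label, and another -0.01 with array quality weights and -0.02 to 0.06 with 1 array left out.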

Other observations

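The genes named here were chosen after their values were seen, apart from those the rule for named genes covers, and no further test was run on them.

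Several genes outside the lists moved together in both tissues. The collagen chaperone gene Serpinh1 rose on both of its probe sets, by 0.60 ± 0.07 and 0.54 ± 0.06 in brain and 1.10 ± 0.08 and 0.60 ± 0.07 in liver. The splicing factor gene Sfpq rose in both tissues on 2 of 6 probe sets, by 0.87 ± 0.12 and 0.42 ± 0.09 in brain and 0.63 ± 0.09 and 0.58 ± 0.10 in liver. The inositol transporter gene Slc5a3 did so on 1 of 3, by 0.64 ± 0.08 and 0.98 ± 0.08. Hnrnpdl, an RNA-binding protein gene, fell in both tissues on 4 of 7 probe sets, from -0.46 ± 0.05 to -0.76 ± 0.12 in brain and from -0.25 ± 0.05 to -0.49 ± 0.08 in liver. The ubiquitin ligase scaffold Cul2 fell on 1 of 2 probe sets, by 0.75 ± 0.12 and 0.52 ± 0.10, while the other gave -0.03 and 0.02. The methionine aminopeptidase Metap2 fell on 1 of 4, by 0.53 ± 0.11 and 0.54 ± 0.12, and the others gave -0.09 to 0.08 in brain and -0.19 to 0.11 in liver. Among the 7 probe sets called in opposite directions, Zfp651 was higher in brain (0.37 ± 0.07) and lower in liver (-0.24 ± 0.06) on 1 of its 3 probe sets, and Reck (-0.44 ± 0.08 and 0.56 ± 0.08), Rasgef1b, Fam214a, Bmyc and Amy1 were lower in brain and higher in liver.

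Pituitary hormone transcripts varied widely between brain arrays. Gh read 5.03, 5.18 and 4.68 on the AKR/J control arrays, 9.83 to 11.41 on the AKR/J sleep-deprived arrays and 4.24 on C57BL/6J sleep-deprived array 3. The change of Gh in AKR/J was 5.78 ± 1.37 with limma's adjusted p = 0.1234. Acute-phase transcripts varied likewise between liver arrays, with Saa2 from 7.02 to 13.52 and Lcn2 from 4.82 to 11.95.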
